A study of Mus musculus with 6 samples.

How the data were processed

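RNA was measured in cultured mast cells of 2 genotypes, WT and miR-155 KO, with 3 independent cultures per genotype according to the labels' protocols. Total RNA was extracted on silica columns, labelled with biotin and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per culture. The deposited values are log2 intensities made by the authors with RMA, per the submitters' processing notes. The version of RMA was not given in the sources used here. RMA corrects the background, normalizes between arrays and summarises the probes of each transcript cluster, so differences between 2 arrays are log2 ratios. The column medians lay between 3.67 and 3.74 and the upper quartiles between 6.01 and 6.09, alike without being identical, and no further normalization was applied. For arrays the number of arrays, here 3 per group, limits the precision.

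The value table had 35557 probe sets. The platform annotation paired 21789 of them with exactly 1 gene symbol and 1621 with several, and did not list 12147, which stay unnamed here. Whether control probe sets are among these was not given in the sources used here. Of the probe sets with 1 symbol, 21698 had an Entrez ID in the RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols needed an update. A gene with more than 1 cluster (999 genes) was represented by the cluster with the highest mean over the 6 arrays, which left 19938 genes. The build behind the array annotation was not given in the sources used here, so the gene table served only for names and for which genes neighbour each other.

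Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without trend or robust options), with genotype as the only term. All tests were two-sided. Every adjusted p is Benjamini-Hochberg adjusted and, unless stated otherwise, comes from this limma fit over the 19938 genes. A gene is said to have risen, fallen or changed where this value was under 0.05. The fit had 4 residual degrees of freedom, and the estimated prior added 4.68. Values are group means ± SD over 3 arrays, differences are miR-155 KO minus WT on the log2 scale, and SE is the moderated standard error of that difference.

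The contrast, the thresholds, 22 gene lists and the rule for naming genes were set before the data were examined. Of the lists, 21 were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 21 lists, and again with the correlation estimated from the data and with fry. The list of sex linked genes was only tabulated. The list of reported miR-155 targets was compiled from general knowledge of other studies, not from these arrays. The genes named are Mir155, the 10 largest increases and the 10 largest decreases among changed genes whose groups do not overlap, up to 4 members of each list with the lowest p, and 12 genes fixed by name (Pik3r5, Pik3r6, Pik3cg, Inpp5d, Tnf, Il6, Il13, Fos, Egr1, Fcer1a, Kit and Cpa3). Numbered gene models, small RNAs and olfactory or vomeronasal receptors were left out of the largest changes, which passed over 3 changed genes (Gm8995, Olfr920 and Snora23). Any other gene named was chosen after its values were seen.

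The alternatives tried were a replicate block, median centring, a repeated quantile normalization, a filter on dim genes, trend and robust priors, array weights, testing every probe set, averaging the clusters of a gene, an ordinary pooled-variance test and leaving out each array in turn. The fits were tested on simulated data with the means and spreads of the 19938 genes, in 20 simulated sets with 200 changed genes each. For the comparison of miR-155 KO with WT, 98.9% of genes changed by 1 log2 unit and 99.95% of those changed by 2 units were recovered, with the right sign in 100% of the recovered genes. Of all calls, 6.98% were false. A list of 40 genes shifted by 0.5 was called in 20 of the 20 sets and an unshifted list in 0. The simulated genes were drawn independently of each other, with moderated spreads and no array lying apart. These rates therefore do not carry over to lists of correlated genes or to arrays of which 1 lies apart. Plots were drawn with matplotlib 3.10.9. A search for miR-155 seed matches in 3' untranslated regions was planned and needs a genome sequence, which was not used here.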

Results

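Gene expression was measured in mast cells grown from the bone marrow of C57BL/6J mice that were wild type (WT) or lacked the microRNA miR-155 (miR-155 KO). Mast cells carry FcεRI, the high-affinity receptor for IgE, and release granules, lipid mediators and cytokines when antigen cross-links the bound IgE. The cells had spent 5 weeks in IL-3 (0.5 ng/ml) and SCF (1 ng/ml). They were loaded overnight with IgE against the hapten DNP at 0.2 µg/ml and then exposed to the antigen DNP-HSA at 20 ng/ml for 1 h. Each genotype had 3 independent cultures with 1 array each, 6 arrays in all. All 6 were taken after stimulation, so the values compare genotypes in stimulated cells and do not measure the response to antigen itself. Across the 19938 genes, which are not independent replicates, Pearson correlations were 0.994 to 0.995 among WT arrays, 0.992 to 0.996 among KO arrays and 0.983 to 0.993 between genotypes. The first principal component held 48.3% of the variance. KO replicate 1 lay apart on it at 32.0, while KO replicates 2 and 3 were at 5.36 and 7.31 and the WT arrays between -19.5 and -10.6.

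The comparison asks how the absence of miR-155 alters gene expression in mast cells responding through FcεRI. The probe set for Mir155, the targeted gene, read 2.99 ± 0.15 in WT and 2.86 ± 0.08 in KO arrays (log2, SD, n = 3), a difference of -0.13 (adjusted p = 0.679). These values lie near the bottom of the arrays' range in both genotypes, so this probe set checks neither the deletion nor the labels.

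Loss of miR-155 was accompanied by higher expression of several genes of inflammatory mediators and of subunits of a phosphoinositide 3-kinase. Tnip3, which encodes an A20-binding inhibitor of NF-κB signalling, rose most, from 4.19 ± 0.38 to 8.16 ± 0.85 (15.7-fold, adjusted p = 0.00531). The interleukin-1 genes Il1b and Il1a rose 9.26-fold and 8.11-fold, and the allergy-associated cytokine gene Il13 rose 6.05-fold. Serpinb9b, a serine protease inhibitor, rose 6.59-fold, Crtam, a cell surface receptor, 5.88-fold, and Car2, a carbonic anhydrase, 5.74-fold. Serpinb9b and Crtam both had WT means of 3.67, at the level of the array medians. Their WT signal may be background, so these 2 folds are not exact. The WT means of Tnip3 (4.19), Il1b (4.13) and Il1a (4.08) lay little above the array medians, and Il1b read 3.56 in WT replicate 3. The folds of Tnip3, Il1b and Il1a may therefore be inexact too. In the other direction, the fatty acid elongase gene Elovl7 fell by 1.62 on the log2 scale (SE 0.20, 3.07-fold lower), Trib2, a pseudokinase, fell by 1.40 (SE 0.21) and Nxn, nucleoredoxin, fell by 1.28 (SE 0.20).

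In total 164 of the 19938 genes changed, 101 higher and 63 lower in miR-155 KO. Changes of at least 2-fold were found for 48 of the higher and 8 of the lower genes, and the median fold was 1.91 over all 101 higher genes and 1.64 over all 63 lower genes. In all 164 genes the 3 KO arrays lay on 1 side of the 3 WT arrays. This held for 17.2% of all genes tested, where chance gives 10%. At a fold of at least 1.5 with an unadjusted p under 0.05 there were 412 genes, 215 higher and 197 lower. The count of changed genes depended strongly on which array was left out. It was 15, 43 and 27 without WT replicates 1, 2 and 3, and 103, 167 and 74 without KO replicates 1, 2 and 3. In all 6 of these fits 12 genes passed, among them Tnip3, Serpinb9b, Pik3r5 and Pik3r6. When all 35557 probe sets were tested, named or not, 4 genes passed (Pik3r6, Gstt1, Gda and Guca2a). Of these probe sets 12147 are not in the annotation, and whether control probe sets are among them was not given. In addition, an ordinary pooled-variance test passed 0 (lowest adjusted p = 0.179, 1986 genes at an unadjusted p under 0.05).

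**Figure D1:**
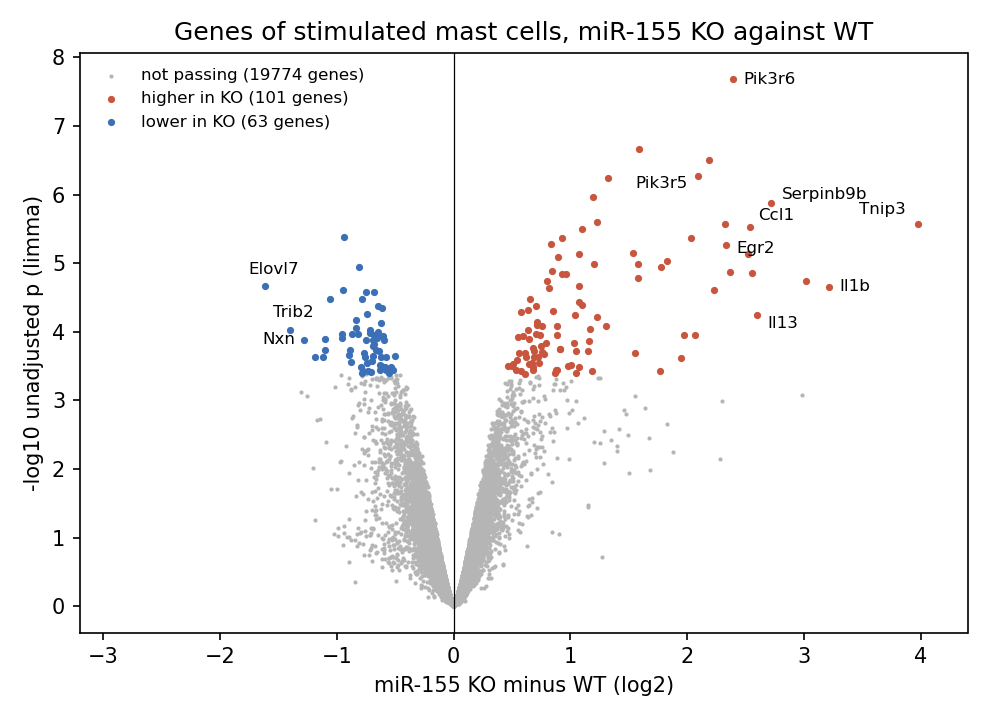
Log2 difference between miR-155 KO and WT (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for the 19938 genes, 1 point per gene. The 101 genes that rose (red) reach larger differences, up to 3.97 for Tnip3, than the 63 that fell (blue), which reach -1.62 for Elovl7.

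Pik3r6 and Pik3r5, which encode the regulatory subunits of the gamma class of phosphoinositide 3-kinase, rose together. Pik3r6 went from 6.26 ± 0.18 to 8.65 ± 0.18 (5.24-fold, SE 0.12, adjusted p = 4.15e-04), the lowest p of all genes tested, and Pik3r5 from 4.48 ± 0.20 to 6.57 ± 0.30 (4.26-fold, SE 0.16, adjusted p = 0.00225). Pik3cg, the catalytic subunit that pairs with them, differed by -0.25 (SE 0.10, adjusted p = 0.335) and Inpp5d, the phosphatase SHIP1 and a known miR-155 target, by -0.28 (SE 0.12, adjusted p = 0.352). Of 37 measured genes of the PI3K pathway 3 rose, 0 fell and 34 did not pass. The third was Foxo1, a transcription factor restrained by this pathway, at 1.46-fold (adjusted p = 0.0400). Adjusted over the list alone, 5 rose and 1 fell, the latter Pik3ip1, an inhibitor of the kinase, at -1.26 (SE 0.25, adjusted p = 0.0653 over all genes, 0.0205 to 0.427 over the alternatives). The list did not shift as a whole (median -0.07, mean 0.09, camera adjusted p = 0.855). Foxo1 passed in none of the fits without 1 array (adjusted p from 0.0526 to 0.138), while Pik3r5 and Pik3r6 passed in all 6. Over every probe set, Pik3r5 was at an adjusted p of 0.0503 and Pik3r6 at 0.0165.

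Cytokine and chemokine genes had the largest mean difference of the 21 lists set beforehand. Of 51 measured, 8 rose, 0 fell and 43 did not pass. The 8 were Il1b, Il1a, Il13, Il9, Ccl1, Ccl3, Ccl9 and Tnfsf14. Ccl1 rose from 9.59 ± 0.50 to 12.12 ± 0.28 (5.80-fold, adjusted p = 0.00531), Ccl3 from 9.11 ± 0.26 to 11.48 ± 0.61 (5.14-fold, adjusted p = 0.00916), Ccl9 by 5.00-fold, and Il13 by 2.60 on the log2 scale (SE 0.36, adjusted p = 0.0203). Tnf at 1.20 (SE 0.31, adjusted p = 0.127) and Il6 at 1.41 (SE 0.34, adjusted p = 0.105) lay above WT on all 3 KO arrays and did not pass. Adjusted over the list alone, 17 rose and 0 fell. The mean of the list differed by 0.63 (camera adjusted p = 1.0e-09), and this was lost with an estimated correlation (adjusted p = 0.734). Against the WT mean, KO replicates 1, 2 and 3 stood at 0.90, 0.36 and 0.65 and the WT arrays between -0.07 and 0.06. The number of list members that rose was 0, 4 and 2 without WT replicates 1, 2 and 3, and 9, 13 and 5 without KO replicates 1, 2 and 3. Among these fits Ccl1 and Ccl9 were lost only without WT replicate 1 (adjusted p = 0.0507 for both). With trend and robust priors Il1b, Il13 and Ccl3 no longer passed. Over all their alternatives the adjusted p ran from 0.00365 to 0.337 for Il1b, from 0.00456 to 0.354 for Il13 and from 0.00251 to 0.337 for Ccl3, each highest in the ordinary test. Tnf and Il6 passed without KO replicate 2 (adjusted p = 0.0179 and 0.0396), within ranges of 0.0179 to 0.505 and 0.0352 to 0.488.

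**Figure D2:**
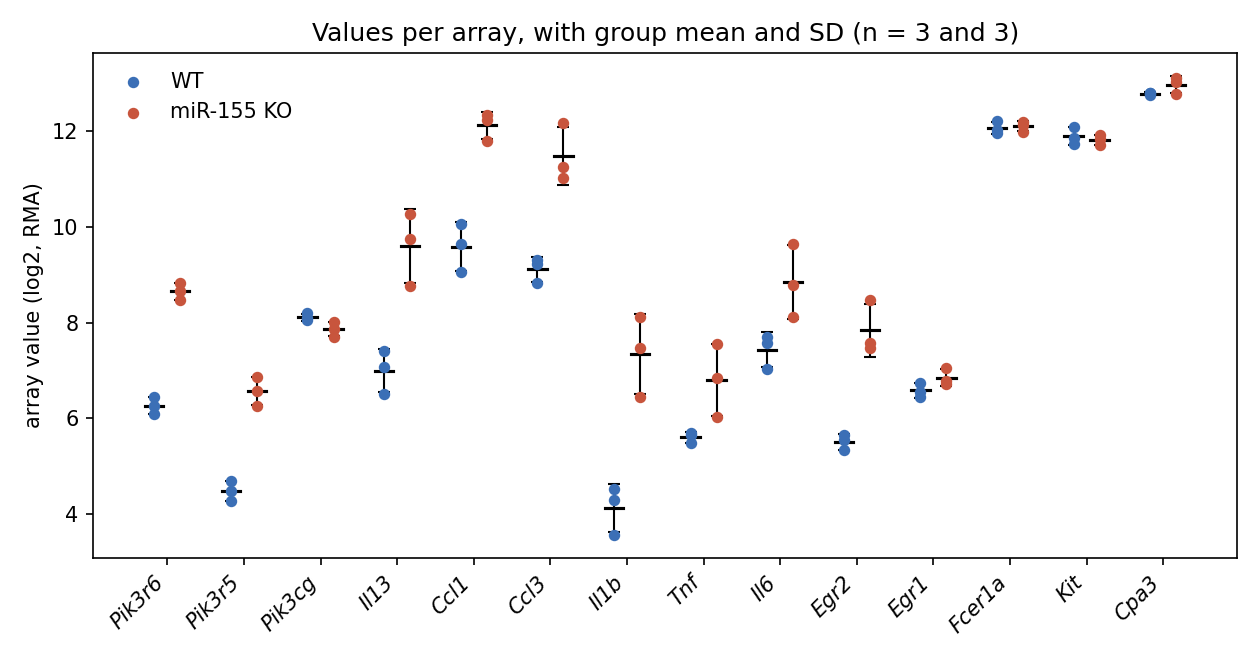
RMA values (log2, vertical axis) of 14 genes on each of the 3 WT (blue) and 3 miR-155 KO (red) arrays, with horizontal bars for group means and error bars for the SD. Pik3r6, Pik3r5, Il13, Ccl1, Ccl3, Il1b and Egr2 are higher on every KO array than on any WT array, while Fcer1a and Kit overlap between the groups.

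Immediate early genes, which are switched on within minutes of receptor signalling, were also higher on average. Of 55 measured, 4 rose, 0 fell and 51 did not pass. Egr2, a zinc finger transcription factor, rose 5.02-fold (SE 0.24, adjusted p = 0.00626), Nfkbia, the NF-κB inhibitor IκBα, 4.19-fold (adjusted p = 0.0280), Gadd45b 2.94-fold and Dusp5, a MAP kinase phosphatase, 2.05-fold. Fos differed by 0.07 (SE 0.22, adjusted p = 0.959) and Egr1 by 0.27 (SE 0.12, adjusted p = 0.392). Adjusted over the list alone 13 rose and 2 fell. The mean difference was 0.40 (camera adjusted p = 1.0e-09, and adjusted p = 0.797 with an estimated correlation), and it was 0.26 without KO replicate 1. KO replicates 1, 2 and 3 stood at 0.68, 0.12 and 0.39 against the WT mean. The number of members that rose was 0, 1 and 1 without WT replicates 1, 2 and 3, and 5, 8 and 1 without KO replicates 1, 2 and 3. Among these fits Egr2 was lost only without WT replicate 1 (adjusted p = 0.0519), and Dusp5 passed only without KO replicate 2. Nfkbia and Gadd45b did not pass with trend and robust priors, and their adjusted p over all alternatives ran from 0.00655 to 0.362 and from 0.0179 to 0.372.

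Genes of the unfolded protein and amino acid stress response were higher on average and genes of hypoxia and glycolysis lower. Of 31 genes of the former list 2 rose, 0 fell and 29 did not pass. Slc7a11, the cystine transporter, rose 3.55-fold (adjusted p = 0.00827) and Asns, asparagine synthetase, 1.55-fold (adjusted p = 0.0269). Both are known targets of the amino acid response, and the chaperone gene Hspa5 differed by 0.35 (SE 0.09, adjusted p = 0.141). Adjusted over the list alone 7 rose and 0 fell. Of 31 hypoxia and glycolysis genes 0 rose, 2 fell and 29 did not pass. Ddit4, a stress-induced inhibitor of mTOR, fell by 0.68 (SE 0.08, adjusted p = 0.0126) and Aldoc, a glycolytic aldolase, fell by 0.82 (SE 0.12, adjusted p = 0.0280), and over the list alone 5 fell and 0 rose. Mean differences were 0.22 (camera adjusted p = 6.5e-07) and -0.23 (camera adjusted p = 3.5e-09). With an estimated correlation both lists had an adjusted p of 0.734. KO replicates 1, 2 and 3 were at 0.29, 0.09 and 0.29 for the first list and at -0.13, -0.32 and -0.23 for the second. Without WT replicate 1, 0 members of either list passed, and Slc7a11 passed in the other 5 of the 6 fits without 1 array. Ddit4 did not pass without WT replicate 1, 2 or 3 (adjusted p from 0.0618 to 0.0656), and of these 6 fits Asns and Aldoc passed only that without KO replicate 2.

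Cell cycle genes were lower on average, with an uneven split among the KO arrays. Of 39 measured, 0 rose, 0 fell and 39 did not pass, and the list alone gave 0 as well (limma), although 38 of 39 had negative differences. E2f1, a transcription factor of S phase entry, differed by -0.65 (SE 0.21, adjusted p = 0.209) and Mcm2, a subunit of the replicative helicase, by -0.68 (SE 0.23, adjusted p = 0.235). The mean difference was -0.50 (camera adjusted p = 2.0e-07, and adjusted p = 0.831 with an estimated correlation). KO replicate 1, the array that lay apart, was at -1.25 against the WT mean, KO replicates 2 and 3 were at -0.32 and 0.07, and WT replicate 2 was at -0.38. The mean difference was -0.13 without KO replicate 1 and -0.78 without KO replicate 3. Cholesterol synthesis genes had a mean difference of -0.10 (camera adjusted p = 0.0205, and adjusted p = 0.831 with an estimated correlation), with 0 of 21 members passing over all genes, 1 up and 2 down over the list alone, and KO replicates 1, 2 and 3 at -0.17, -0.12 and -0.01. Its mean was -0.06 without WT replicate 3 and -0.06 without KO replicate 1, and the list passed in neither of these fits nor without KO replicate 2 (mean -0.09).

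**Figure D3:**
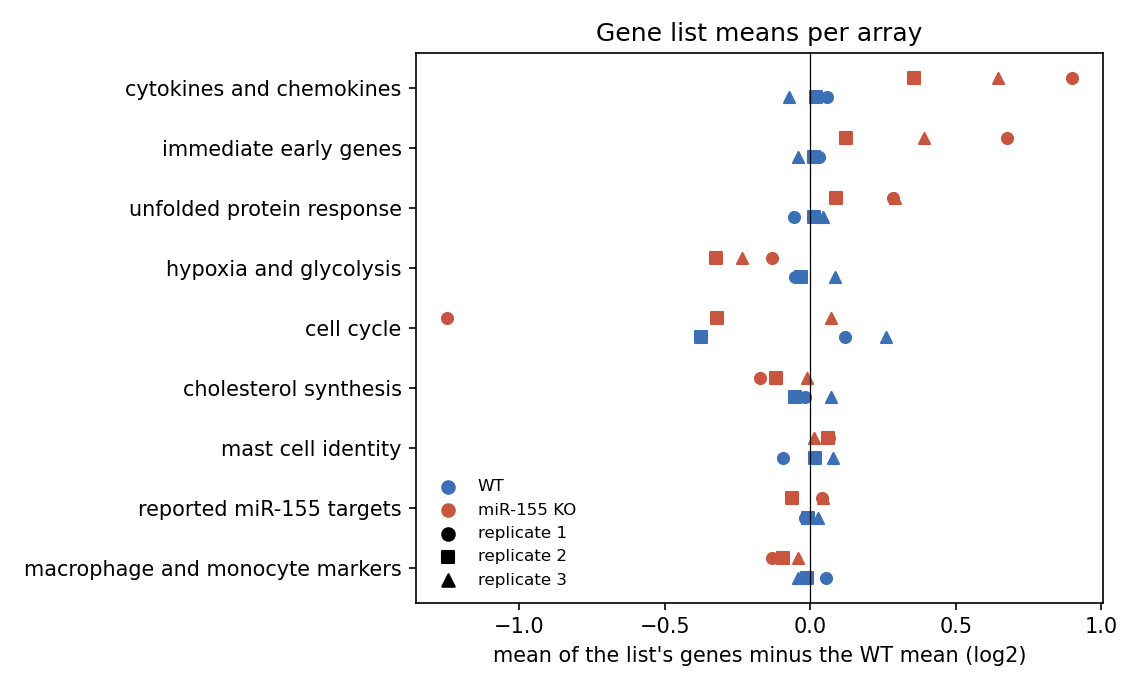
Mean log2 value of the genes of 9 lists on each array, minus the mean of the WT arrays (horizontal axis), for WT (blue) and miR-155 KO (red), with the marker shape giving the replicate. The 3 KO arrays lie above all WT arrays for cytokines and chemokines (0.36 to 0.90), while for the cell cycle KO replicate 1 stands alone at -1.25.

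Mast cell identity genes did not shift as a list, and single members went both ways. Of 34 measured, 0 rose and 0 fell by limma, over all genes or over the list alone, with a mean difference of 0.05 and a median of -0.00 (camera adjusted p = 0.896). Fcer1a, the IgE-binding chain of the receptor, read 12.06 ± 0.13 in WT and 12.10 ± 0.10 in KO, Kit, the SCF receptor, 11.89 ± 0.19 and 11.82 ± 0.10, and Cpa3, a granule protease, 12.78 ± 0.03 and 12.97 ± 0.18. The 4 members with the lowest p were Mcpt4 at 0.44 (SE 0.13), Slc6a4, the serotonin transporter, at -0.75 (SE 0.24), Hdc, histidine decarboxylase, at 0.84 (SE 0.28) and Maob at -0.28 (SE 0.10). Their adjusted p lay between 0.174 and 0.270, none passed under any alternative, and the groups did not overlap for Mcpt4, Hdc and Maob. Of 49 genes of proximal FcεRI signalling 1 rose, 0 fell and 48 did not pass. This was Stim2, a calcium sensor of the endoplasmic reticulum, at 1.81-fold (adjusted p = 0.0190), and it did not pass without WT replicate 1, 2 or 3 or KO replicate 3 (adjusted p from 0.0663 to 0.0819). Its relative Stim1 differed by -0.46 (SE 0.10, adjusted p = 0.0747) and the inhibitory kinase Csk by -0.58 (SE 0.11, adjusted p = 0.0531, and 0.0314 to 0.354 over the alternatives). Over the list alone 4 rose and 7 fell, and the list did not shift (camera adjusted p = 0.591). Of 42 degranulation genes 0 passed and 2 fell over the list alone, Rab27a at -0.62 (SE 0.11, adjusted p = 0.0523 over all genes, and 0.0307 to 0.355 over the alternatives) and Lyst at -0.58 (SE 0.12), with no shift of the list (camera adjusted p = 0.591). Among 27 eicosanoid genes Ptgs2, cyclooxygenase 2, rose 3.86-fold (adjusted p = 0.0386), 0 fell and 26 did not pass, while over the list alone 2 rose and 1 fell (camera adjusted p = 0.878). Ptgs2 did not pass without WT replicate 1, 2 or 3, without KO replicate 3 or with trend and robust priors, and its adjusted p over all alternatives ran from 0.0143 to 0.372. The WT mean of Ptgs2 was 3.99, little above the array medians, so its fold may be inexact.

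Transcripts reported as miR-155 targets in other systems did not rise as a group. Of 65 measured, 0 rose and 0 fell by limma over all genes, and 2 rose and 4 fell over the list alone. Tbc1d14, the member with the lowest p, differed by -0.36 (SE 0.08, adjusted p = 0.0815). Ptprj, a receptor phosphatase, differed by 0.78 (SE 0.18, adjusted p = 0.0962), and its second probe set by 1.03. Irak3, an inhibitor of Toll-like receptor signalling, differed by -0.80 (SE 0.17, adjusted p = 0.0828). Bcl6, a transcriptional repressor, differed by -0.55 (SE 0.13, adjusted p = 0.0975). The median difference was -0.00 and the mean 0.01 (camera adjusted p = 0.930).

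Markers of other blood and stromal cells showed few differences. Of 19 macrophage and monocyte genes Cx3cr1, the fractalkine receptor, fell by 0.95 (SE 0.14, adjusted p = 0.0280) and 18 did not pass (camera adjusted p = 0.439). Of 13 erythroid and megakaryocyte genes Car2 rose and 12 did not pass, with a median of -0.07 and a mean of 0.18 (camera adjusted p = 0.653). By limma 0 passed of 18 neutrophil (camera adjusted p = 0.877), 15 basophil and eosinophil (0.674), 17 dendritic cell (0.653), 22 lymphocyte (0.591), 18 stromal (0.841) and 29 interferon response genes (0.896). Over each list alone 1 dendritic cell gene, H2-Ab1, fell, as did 1 interferon response gene, Irf1, whose second, dimmer probe set differed by 0.10. Among 30 genes flanking Mir155 on chromosome 16, 0 passed (camera adjusted p = 0.877). Cx3cr1 passed only without KO replicate 2 (adjusted p from 0.0178 to 0.0911 over the 6 fits without 1 array). Xist read 9.01 ± 0.32 in WT and 9.14 ± 0.04 in KO arrays, and the Y-linked genes Eif2s3y, Kdm5d and Uty had group means between 2.39 and 2.77, and 0 of these 4 genes differed by limma (lowest adjusted p = 0.612, with 0 at an unadjusted p under 0.05).

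Among the other genes with the largest decreases, Lpcat2, an acyltransferase of platelet-activating factor synthesis, fell by 1.18 (SE 0.20, adjusted p = 0.0375) and Pitpnc1, a phosphatidylinositol transfer protein, fell by 1.10 (SE 0.18, adjusted p = 0.0354). Gp5, a platelet glycoprotein, fell by 1.11 (SE 0.19) and Slc45a3, a solute carrier, fell by 1.10 (SE 0.17). Gpr137b, a lysosomal membrane protein, fell by 1.05 (SE 0.14) and Kazald1 fell by 0.96 (SE 0.15). Of the 10 largest decreases 0 passed without WT replicate 1, 2 or 3, and the highest adjusted p of each without 1 array lay between 0.0678 and 0.142. Of the 10 largest increases, Crtam, Car2, Il1b and Ccl3 were lost without WT replicate 1 or WT replicate 3. The highest adjusted p of each was 0.0620, 0.0519, 0.0620 and 0.0555. Il1a was lost without WT replicate 1, 2 or 3 (highest adjusted p = 0.0678). Il13 was lost in these 3 fits and also without KO replicate 3 (highest adjusted p = 0.0940). Ccl1 was lost without WT replicate 1 (adjusted p = 0.0507), while Tnip3, Serpinb9b and Pik3r6 passed in every fit without 1 array.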

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

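The alternatives were set beforehand, except for those that changed only the prior or the number of tests, the list counts without each array, and the values of single genes over every probe set, with averaged clusters and in the ordinary test, which were chosen after seeing the data. The 164 changed genes became 190 after median centring, 203 after a repeated quantile normalization, 224 among genes above the median signal, 230 with trend and robust priors, 188 with array weights and 167 with clusters averaged. All 164 kept their direction in these settings where tested (161 in the filter). Leaving out a single array could not reverse a direction, because the groups of all 164 genes do not overlap. The kept directions are therefore no sign of stability, and the count ran from 15 to 167 when any single array was left out. Testing every probe set left 4. Adjusting over that many tests with the prior of the named genes gave 69, and taking the prior from every probe set with the adjustment over the named genes gave 15, so both parts lowered the count. The prior degrees of freedom were then 2.90 in place of 4.68, and probe sets without a single symbol, which may include controls, had a median residual SD of 0.19 against 0.12. With every probe set the count at 1.5-fold and unadjusted p under 0.05 was 754 in place of 412: 393 among the tested genes under that prior and 361 further probe sets. The ordinary pooled-variance test gave 0 changed genes, since it has 4 degrees of freedom and no prior. The 6 shifted lists became 0 with an estimated correlation and 0 with fry. The estimated correlations between the genes of these lists, 0.20 to 0.92, lay above the preset 0.01 and gave each list its highest adjusted p, while the lowest over the alternatives ran from 6.8e-17 to 0.00234 and fry asks another question. Cholesterol synthesis was the only list lost elsewhere, in 5 more settings. A replicate block gave 199 changed genes (129 shared with the 164), 430 genes by fold and 6 lists. Same-numbered arrays deviated with correlations of -0.01, -0.06 and 0.24, and not every array correlated best with its own number. With 3 arrays per group these values cannot tell whether the numbers pair the cultures. Among gene values under the alternatives 1714 stayed on their side of the threshold, 318 no longer passed and 28 newly passed. The 1714 include values of genes that did not pass in the main fit either, so they do not measure the stability of the changed genes. Of the values that passed in the main fit or in the alternative, 0 reversed direction. Sign changes of genes that passed in neither were not counted. Probe sets near the bottom of the range, such as that of Mir155, limit what can be seen. The seed match test was not run.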

Other observations

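All 6 gene lists in the next 2 paragraphs, the test of neighbouring genes and the tests of single explanations were chosen only after the results were seen, while the counts over other splits of the arrays were planned.

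Of 23 measured regulators and feedback inhibitors of NF-κB 7 rose, 0 fell and 16 did not pass, and 4 of the 23 had negative differences. Beside Tnip3 and Nfkbia these were Nfkbib (1.84-fold), Bcl3 (1.82-fold), Tnip1 (1.64-fold), Relb (1.60-fold) and Ikbkg (1.55-fold). Targets of the oxidative stress factor NRF2 had 6 risen, 1 fallen and 18 not passing of 25, with Slc7a11 at 3.55-fold, Srxn1, sulfiredoxin, at 1.64-fold, Txnrd1, thioredoxin reductase, at 1.49-fold and Pgd, of the pentose phosphate pathway, at 1.51-fold. Gclm and Nqo1 were the other 2 that rose, and Osgin1 fell by 0.64. These lists were drawn up around genes already seen to change, so their counts are not independent evidence and no test of them is given. Of their members, Bcl3, Relb, Pgd, Gclm, Nqo1 and Osgin1 each passed in 0 of the 6 fits without 1 array.

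Single members of 4 further lists rose while most members did not pass. Gzmd and Gzme, neighbouring granzyme genes, rose 4.70-fold and 2.24-fold among 11 granzyme and perforin genes, of which Gzmb differed by -0.21 (adjusted p = 0.729). The WT means of Gzmd and Gzme were both 2.97, near the bottom of the arrays' range, so these folds are not exact. Similarly, Serpinb9b, Serpinb9 and Serpinb6b, serine protease inhibitors, rose 6.59-fold, 2.99-fold and 2.99-fold among 11 related serpins. The WT means of Serpinb9b and Serpinb6b were 3.67 and 3.87, at or just above the array medians. The WT signal of Serpinb9b and Serpinb6b may be background, so their folds are not exact either. Members of both families are close in sequence, so cross-hybridisation between copies was not excluded. Ahr, Cyp1b1 and Nqo1 rose among 9 genes of the aryl hydrocarbon receptor response, and Casp1 (1.63-fold) and Casp4 (2.27-fold) among 10 inflammasome genes. The WT mean of Casp4 was 3.89, close to that of Serpinb6b, so the fold of Casp4 is not exact. These 4 lists too were built around genes already seen to change, so the same holds for them. Of the 6 fits without 1 array, Nqo1 passed in 0, Ahr and Cyp1b1 in 1, Casp1 and Casp4 in 2, Gzme in 3, and Gzmd, Serpinb9 and Serpinb6b in 4. Each was lost without WT replicate 1 and also without WT replicate 3 (adjusted p from 0.0517 to 0.147). Changed genes formed 11 adjacent pairs in the gene order, against a mean of 1.33 and a maximum of 8 in 10000 permutations (permutation p = 1e-04, the smallest they can give). The pairs include Pik3r5 with Pik3r6, Il1a with Il1b and Casp1 with Casp4, and several are family members. In the pair of Maml3 (-0.59) and Foxo1 (0.54) the directions were opposite. Such pairs had been seen before the test was chosen, and the permutations treat neighbours as unrelated. This p is therefore not independent evidence.

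The mean of the cytokine and chemokine genes was higher on all 3 KO arrays than on any WT array. Of the 51 members 43 did not pass and 16 had negative differences, and the shift of the list was lost with an estimated correlation (adjusted p = 0.734). Macrophages or monocytes in the KO cultures would bring their own transcripts, but the upper quartile of the differences of that marker list was 0.058. Single markers went both ways: Cx3cr1 fell, while Vcan, versican, was higher on every KO array (1.70-fold, adjusted p = 0.178) and passed without KO replicate 2 (adjusted p = 0.0437, and 0.0437 to 0.542 over the alternatives). KO replicate 1 alone does not account for it, since the lower of the other 2 KO arrays exceeded the highest WT array by 0.30 in the list mean, against a range of 0.13 among WT arrays. The list mean was 0.65 after median centring and 0.64 after quantile normalization. The array medians lay between 3.67 and 3.74 beforehand, so these steps could move the mean little and are a weak test of array scaling. A stronger or longer response to antigen in the absence of miR-155 may underlie the pattern, and so may a difference that was there before stimulation, which these stimulated cultures leave open.

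Pik3r5 and Pik3r6 are neighbours on chromosome 11 with 0 tested genes between them. A change of the whole region would move the genes around them, and the upper quartile of the differences of the 20 nearest tested genes was 0.17 (median 0.06). On 1 side, however, the adjacent Mfsd6l rose by 0.50 and Myh10, 2 genes beyond it, differed by 0.87 (SE 0.17, adjusted p = 0.0548), so a change of fewer neighbours stays open. KO replicate 1 alone does not explain them, since the lower of the other 2 KO arrays exceeded the highest WT array by at least 1.59 for both genes, against a WT range of 0.41. How the 2 genes are controlled was not tested, nor was a difference at this locus between the mouse stocks.

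The lower cell cycle values may come from KO replicate 1 alone. KO replicates 2 and 3, at -0.32 and 0.07 against the WT mean, lay within the WT range of -0.38 to 0.26. The lowest WT array minus the higher of KO replicates 2 and 3 was -0.45, against a range of 0.64 among WT arrays. The list mean went from -0.50 to -0.13 without KO replicate 1. Whether that culture grew more slowly or its RNA differed for another reason was not tested.

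DNA of a donor strain around the targeted locus could have brought changed genes near Mir155. The 200 tested genes around it held 1 changed gene, Ifnar1 (log2 difference 1.10), 69 tested genes away. Of 15845 windows of that size 76.5% held as many, and the median window held 1. A count this low cannot tell whether donor DNA was present. Ifnar1 passed in all 6 fits without 1 array, which does not bear on its cause, and this explanation stays open. The splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The 1 real split gave 164 changed genes, with 1 as the highest of the others, and 412 genes by fold, with 165 as the highest other. For lists 2 of the 10 splits gave 6, the real one and the one that set WT replicate 1 with KO replicates 1 and 2. Each of the other splits also called at least 1 list. Camera at the preset correlation thus called lists for groups that mix the genotypes. A list called at this setting is not by itself evidence of a genotype difference.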
